A study of Caenorhabditis elegans with 15 samples.

How the data were processed

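RNA from whole Caenorhabditis elegans N2 larvae was sequenced in 15 libraries, 3 for each of 5 groups: empty-vector control RNAi at 24 h, and egl-45 RNAi and rps-11 RNAi at 48 h and at 120 h. Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of FPKM values per gene and library (fragments scaled to gene length and library depth), with 20541 genes, and 4 tables that compare an RNAi group with the control. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 were used with build ce11, and the notes do not state the role or settings of each. Whether the gene counting used strand is not given in the sources used here. Per the file headers, each of the authors' comparison tables holds a read count signal per group, averaged by the authors after scaling between libraries, a log2 fold change and a p-value with its adjusted value. In those deposited tables the log2 fold change is the ratio of both group means with no pseudocount, so that it is infinite where 1 of them is 0. All 15 FPKM columns were used, and 0 columns of per-sample values were left out.

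Gene symbols were matched to the deposited gene identifiers for 19587 genes, and 954 kept their identifier. Coordinates came from an Ensembl gene annotation of the assembly that ce11 denotes. In the deposited values, 461 genes were at 0 in every library. FPKM values are not counts, so no count model was fitted. The depth was estimated from the low values: a gene's FPKM multiplied by its exon length (known for 20194 genes) moves in steps of what 1 read is worth. Between 34.8% and 39.3% of values of up to 20 reads fell within 0.05 of a whole number of reads, where 10% would by chance. The annotation behind the authors' gene lengths is not stated, and why the other values lay off whole numbers was not tested. The estimate was 21.23 to 24.3 M reads per library in the control, 23.55 to 25.44 at 48 h and 20.57 to 23.68 at 120 h of egl-45 RNAi, and 18.01 to 24.09 at 48 h and 19.44 to 23.22 at 120 h of rps-11 RNAi. At such depths 1 read in a gene of ordinary length lies far below an FPKM of 1. Libraries of a group were compared in pairs by a chi-square over the estimated reads of genes with at least 20 reads in both together, to look for a library deposited again.

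The values were tested as deposited, without further scaling between libraries, as log2(FPKM + 1), for 14514 genes with a mean FPKM of at least 1 over all libraries. All 15 libraries entered 1 linear model with a term per group (limma 3.58.1 in R 4.3.3, empirical Bayes moderation with an intensity trend), so that all groups shared 1 estimate of the spread. The 9 contrasts were taken from it, and p-values were adjusted over all tested genes of a contrast by the Benjamini-Hochberg method, with a threshold of 0.05. A further count took genes that also changed at least 2-fold on the log2(FPKM + 1) scale. Genes and gene lists were each adjusted within a contrast.

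Gene lists for 42 pathways, tissues, stages and stress responses were fixed beforehand, and 40 with at least 5 tested members were tested with camera at a preset correlation of 0.01. The yolk protein list had 3 tested members and is given as values, and a list of genes encoded in the mitochondrial genome matched no gene of the table. Beside the camera result of each called list in the text of the comparisons stands the adjusted p with the correlation estimated per list. Adjustment over the list alone means that the limma p-values were adjusted over that list's tested members.

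The genes named in the text were chosen by a rule. The targets egl-45 and rps-11 were named in every comparison. In each comparison with the control the 6 largest rises and 6 largest falls could be named, among genes with an adjusted p under 0.05, a mean FPKM of at least 5 in the higher group and all 3 libraries of 1 group above all 3 of the other. In the other 5 contrasts the 5 largest rises and falls by the same rule could be named. In each list, up to 3 called members with the largest change in the direction of the list's median, and the 1 with the largest change the other way, could be named. The text prints a selection of these.

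Each result was recomputed with pseudocounts of 0.1 and 5, with no filter on low values, with a mean FPKM of at least 5, after median-of-ratios scaling, after quantile normalization, without the intensity trend, with only the libraries of the groups compared, with the replicate number as a block, and with each of the 15 libraries left out in turn. Lists were also tested with the estimated correlation and with fry, which asks whether the genes of a list move 1 way on balance and compares them with no other genes. The model, the lists, the named-gene rule and these alternatives were fixed before the data were examined. A fit without the rps-11 RNAi 120 h libraries was added after the data were seen.

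The model was tested on simulated data drawn from the control means and the fitted spread of each gene, with 14514 genes, of which 200 among those with a control value over 2 on the log2(FPKM + 1) scale were changed in the egl-45 RNAi 48 h group, in each of 5 runs. It called 80% of genes changed by 0.5 on the log2 scale, 99.7% of those changed by 1 and 100% of those changed by 2, with 9.6 false calls per run on average. A shift of 0.3 in 1 of 40 lists was called in 5 of 5 runs, and 0 other lists were. Genes were simulated independently, so that this test says nothing of lists whose members vary together. In the real comparisons with the control 72.5% to 83.5% of the tested genes were called, far more than were changed here. The rates of this test therefore do not carry over to those comparisons. The overlap and covariance that the spread between shared control libraries alone would give were estimated from 20 simulations of unchanged groups. Tables were joined and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.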

Results

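Gene expression was profiled by RNA sequencing in whole wild-type (N2 Bristol) Caenorhabditis elegans larvae in which protein synthesis was reduced by feeding RNAi. The RNAi was directed against egl-45, which encodes the eIF3a subunit of translation initiation factor eIF3, or against rps-11, which encodes a protein of the small ribosomal subunit. Synchronized L1 larvae were placed on bacteria carrying the RNAi construct or, as the control, the empty vector L4440. Control animals were collected after 24 h without arrest, and egl-45 and rps-11 RNAi animals after 48 h or 120 h, which the submitters describe as arrested at the L2 larval stage. The 15 libraries formed 5 groups of 3. The control was sampled at 24 h alone, so each comparison with it joins the effect of RNAi with that of a longer time on food. The labels do not say whether the libraries of a group came from separate cultures, and p-values therefore measure the spread between these libraries, which may be technical.

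The deposited values are FPKM, and the steps between low values gave an estimated depth of 18.01 to 25.44 M counted reads per library. Libraries of the same group correlated at 0.9935 to 0.9973 across genes, which are not independent replicates. No pair was close enough to be 1 library deposited again, the mean chi-square per gene being 3.78 to 25. The first principal component, with 56.9% of the variance, parted the control libraries from all RNAi libraries. Of 20541 genes, 14514 with a mean FPKM of at least 1 were tested with limma on log2(FPKM + 1). Log2 changes are given with their standard error (SE) and FPKM values as mean ± SD (n = 3 libraries per group). On this scale the change of a gene with low values is understated. A gene rose, fell, was higher or was lower only where its Benjamini-Hochberg adjusted p in limma passed 0.05. Gene lists were tested with camera, and list medians are medians of log2 changes.

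**Figure D1:**
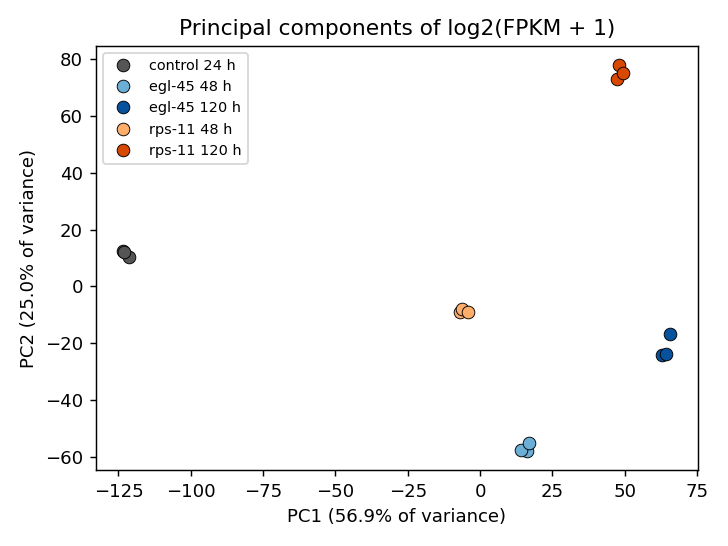
Scores of the 15 libraries on the first principal components of log2(FPKM + 1), PC1 (56.9% of the variance) against PC2, 1 point per library and 1 color per group. The 3 control libraries lie between -123.4 and -121.2 on PC1 and the RNAi libraries between -7.09 and 65.8.

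The targeted genes were examined first. The egl-45 transcript (chromosome III, 7824377 to 7828626, minus strand, build ce11) stood at 103 ± 0.793 FPKM in the control. It stood at 40.1 ± 3.6 (38.7% of the control mean) after 48 h of egl-45 RNAi and at 57.9 ± 3.27 (55.9%) after 120 h. It fell by 1.35 on the log2 scale at 48 h (SE 0.07, limma adjusted p = 6.7e-11) and fell by 0.83 at 120 h (SE 0.07, adjusted p = 1.9e-08). In the rps-11 RNAi libraries egl-45 stood at 96.7 ± 6.74 and 98.9 ± 4.88 FPKM and was not called (adjusted p = 0.21 and 0.39). Under median-of-ratios scaling both values passed the test as lower, at -0.35 and -0.37 on the log2 scale.

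The rps-11 transcript (chromosome IV, 11602641 to 11603280, plus strand, build ce11) stood at 3100.4 ± 26.9 FPKM in the control. It stood at 825 ± 156 (26.6%) after 48 h of rps-11 RNAi and at 1068 ± 48.4 (34.5%) after 120 h. It fell by 1.93 (SE 0.10, limma adjusted p = 1.0e-10) and fell by 1.54 (SE 0.10, adjusted p = 9.6e-10). After egl-45 RNAi rps-11 stood at 3760.1 ± 172 FPKM at 48 h, where it rose by 0.28 (SE 0.10, adjusted p = 0.024), and at 3396 ± 315 at 120 h, where it was not called (adjusted p = 0.26). That rise lost its call under median-of-ratios scaling (0.07), under quantile normalization (0.03) and on leaving out control replicate 3 (0.27) or egl-45 RNAi 48 h replicate 1 (0.24). Each of the 12 RNAi libraries had its own target below every control library.

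**Figure D2:**
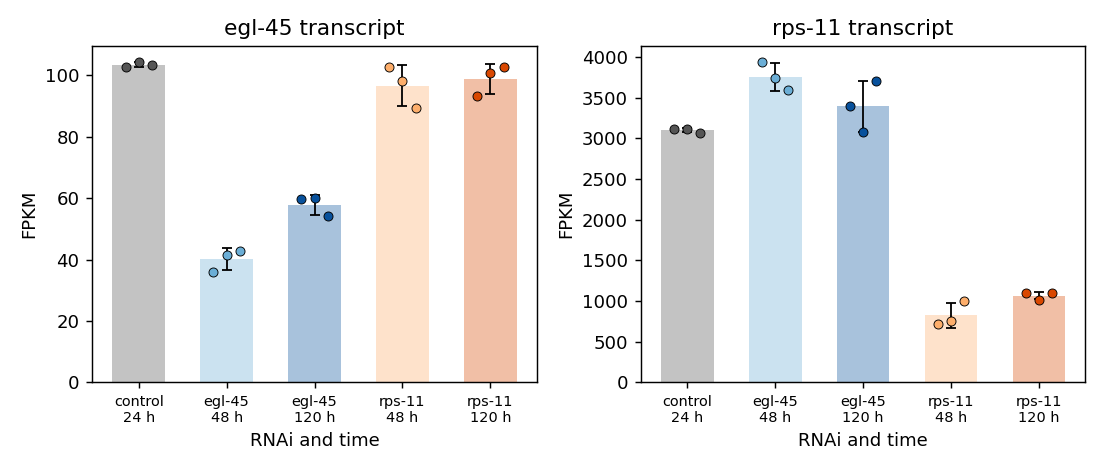
FPKM of egl-45 (left) and rps-11 (right) in the 5 groups, with bars for the mean of 3 libraries, error bars for the SD and points for single libraries. The egl-45 transcript was lowest under egl-45 RNAi at 48 h (40.1 FPKM) and the rps-11 transcript under rps-11 RNAi at 48 h (825 FPKM).

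After 48 h of egl-45 RNAi, innate immunity, pathogen response and cytochrome P450 genes were higher and genes that build the cuticle were lower than in the 24 h control. Camera called 23 of 40 lists at its preset correlation, 0 with an estimated one (8 at an unadjusted p under 0.05), and fry called 38. The infection response gene irg-5 (chromosome V, 13737010 to 13738474, build ce11) went from 7.36 ± 0.379 to 1142 ± 29.1 FPKM, a log2 change of 7.09 ± 0.13 (limma adjusted p = 4.0e-16). The lysozyme gene ilys-3 rose by 6.74 ± 0.16. The beta-tubulin gene tbb-6 (chromosome V, 12261531 to 12263368) rose by 7.37 ± 0.05, from 2.76 ± 0.251 to 618 FPKM. The largest rise by the fixed rule belonged to B0563.9 (chromosome X, 9168539 to 9169096), from 0.122 ± 0.106 to 313 ± 4.98 FPKM. The largest falls were those of C02E7.6, with a log2 change of -9.15 ± 0.24, and of the cuticle collagen gene col-73, with -8.86 ± 0.35, from 4052 ± 187 to 8.62 ± 4.54 FPKM. Of 14514 genes, 10526 were called, 6414 higher and 4112 lower, and 3502 of them changed at least 2-fold (2171 higher, 1331 lower).

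Of 29 PMK-1 innate immunity genes, 28 rose, 0 fell and 1 was not called (median 1.66, camera adjusted p = 7.5e-09, adjusted p = 0.082 with an estimated correlation). This list holds immune genes and also components of the PMK-1 p38 kinase pathway itself, such as pmk-1 and sek-1. It is not a list of targets of that pathway alone. Among its members were irg-5, ilys-3 and sysm-1 (5.2 ± 0.20). Of 37 intracellular pathogen response genes, 32 rose, 2 fell and 3 were not called (median 0.96, camera adjusted p = 6.7e-05, adjusted p = 0.24 with an estimated correlation). The family member pals-6 rose by 3.5. Of 48 epidermal antimicrobial peptide genes, 32 rose, 7 fell and 9 were not called (median 1.01, camera adjusted p = 0.019, adjusted p = 0.69 with an estimated correlation). Here nlp-27 rose by 4.05, while nlp-24 had a log2 change of -3.1. Of 60 xenobiotic cytochrome P450 genes, 52 rose, 2 fell and 6 were not called (median 1.04, 53 risen and 2 fallen adjusted over the list alone, camera adjusted p = 4.8e-08, adjusted p = 0.36 with an estimated correlation). They were led by cyp-35B2 (4.67 ± 0.14) and cyp-35B1 (4.44 ± 0.13). Of 26 DAF-16 activated genes, 20 rose, 4 fell and 2 were not called (median 1.13, camera adjusted p = 5.8e-04, adjusted p = 0.082 with an estimated correlation). This list, of genes turned on by the FOXO factor DAF-16, included the metallothionein gene mtl-1 (6.01) and the lysozyme gene lys-7 (4.79).

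Of 59 neuropeptide genes, 57 rose, 0 fell and 2 were not called (median 1.14, camera adjusted p = 1.5e-09, adjusted p = 0.33 with an estimated correlation). Among them nlp-2 rose by 2.51. Of 50 autophagy and lysosome genes, 32 rose, 5 fell and 13 were not called (median 0.29, camera adjusted p = 0.011, adjusted p = 0.43 with an estimated correlation). The call was lost under median-of-ratios scaling (camera adjusted p = 0.054). The homologs of p62 and LC3, sqst-1 and lgg-2, rose by 2.2 and 1.94. The list of 26 SKN-1 phase II detoxification genes was not called at 48 h (8 rose, 11 fell, camera adjusted p = 0.34) or at 120 h of egl-45 RNAi (8 rose, 13 fell, camera adjusted p = 0.074). In this and the next 3 comparisons, counts adjusted over the list alone equal those over all genes unless another is given.

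Of 137 cuticle collagen genes, 90 fell, 31 rose and 16 were not called (median -1.63, camera adjusted p = 3.2e-10, adjusted p = 0.095 with an estimated correlation). The log2 change was -8.0 for sqt-1 and -7.97 for sqt-3, while col-96 rose by 6.33. Of 53 moulting and apical matrix genes, 41 fell, 9 rose and 3 were not called (median -2.07, camera adjusted p = 2.7e-11, adjusted p = 0.20 with an estimated correlation). The ground-like gene grl-7 and the hedgehog-like gene wrt-4 changed by -7.88 ± 0.17 and -6.48. Of 45 muscle genes, 31 fell, 4 rose and 10 were not called (median -0.37, camera adjusted p = 3.1e-06, adjusted p = 0.40 with an estimated correlation). The troponin T gene mup-2 changed by -1.63. Of 52 nuclear oxidative phosphorylation genes, 49 fell, 1 rose and 2 were not called (median -0.58, camera adjusted p = 2.7e-11, adjusted p = 0.082 with an estimated correlation). The largest change was that of cox-17, -1.22. Of 39 proteasome genes, 32 fell, 6 rose and 1 was not called (median -0.60, camera adjusted p = 3.6e-08, adjusted p = 0.24 with an estimated correlation). The proteasome gene rpn-12 changed by -0.96.

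Of 60 DNA replication and cell cycle genes, 40 fell, 8 rose and 12 were not called (median -0.47, camera adjusted p = 9.9e-07, adjusted p = 0.49 with an estimated correlation). The Aurora kinase gene air-1 changed by -1.96 ± 0.08 and the ribonucleotide reductase gene rnr-1 by -1.54. Of 21 mitochondrial unfolded protein response genes, 13 fell, 5 rose and 3 were not called (median -0.41, 5 risen and 14 fallen adjusted over the list alone, camera adjusted p = 0.0068, adjusted p = 0.32 with an estimated correlation). The chaperone genes hsp-60 and hsp-6 changed by -2.05 and -1.34. Of 32 small-subunit ribosomal protein genes, 23 rose, 0 fell and 9 were not called (median 0.33, camera adjusted p = 0.015, adjusted p = 0.74 with an estimated correlation). That call was lost under median-of-ratios scaling and quantile normalization (camera adjusted p = 0.098 and 0.13). Of 46 large-subunit ribosomal protein genes, 26 rose, 2 fell and 18 were not called (median 0.32, camera adjusted p = 0.050, adjusted p = 0.78 with an estimated correlation). It was lost likewise under both scalings (0.19 and 0.082) and on leaving out any 1 control library, egl-45 RNAi 48 h replicate 1 or 2, egl-45 RNAi 120 h replicate 1 or rps-11 RNAi 48 h replicate 2 (0.050 to 0.10). The median change of all genes was 0.15 as deposited and 0.003 under median-of-ratios scaling. Of the called genes 60.9% were higher as deposited, 48.2% under median-of-ratios scaling and 54% under quantile normalization.

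After 120 h of egl-45 RNAi cuticle genes were lower, and cytochrome P450, sperm and germline transcripts higher, than in the 24 h control. Of 40 lists, camera called 20 at its preset correlation and 0 with an estimated one (6 at an unadjusted p under 0.05), and fry called 37. The collagen genes col-73, col-17, sqt-3 and dpy-13 changed by -10.42 ± 0.35, -10.31 ± 0.24, -10.17 ± 0.22 and -9.94 ± 0.24 on the log2 scale. For example, sqt-3 stood at 3861 ± 291 FPKM in the control and at 2.59 ± 1.74 at 120 h. The largest fall by the fixed rule was that of F41F3.3, -11.13 ± 0.20 (limma adjusted p = 2.8e-16). The lysozyme gene ilys-3 rose by 8.74 ± 0.16, irg-5 by 7.39 ± 0.13, tbb-6 by 7.72 ± 0.05 and B0563.9 by 9.02 ± 0.22. The collagen gene col-143 rose, from 0.0278 ± 0.0241 to 268 ± 15.5 FPKM (limma adjusted p = 6.1e-16). In all, 11938 genes were called, 7761 higher and 4177 lower, with 3535 higher and 1748 lower by at least 2-fold.

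Of 41 sperm genes, 41 rose, 0 fell and 0 were not called (median 3.0, camera adjusted p = 4.7e-09, adjusted p = 0.35 with an estimated correlation). The major sperm protein genes msp-57 and msp-59 and the gene ssq-4 were listed at 0 in every control library and stood at 30.3 ± 4.82, 21.9 ± 3.72 and 23.5 ± 3.27 FPKM. For the 22 members listed at 0 in the control the log2 change depends on the pseudocount, and over the other 19 the median was 2.75. Of 53 germline genes, 48 rose, 2 fell and 3 were not called (median 1.04, camera adjusted p = 1.3e-05, adjusted p = 0.52 with an estimated correlation). The synaptonemal complex gene syp-1 rose by 2.87 ± 0.08 and the meiotic axis gene him-3 by 2.56. Of the yolk protein genes, too few for a list test, vit-6 rose by 2.47 ± 0.21 and vit-2 by 2.14 ± 0.24, and vit-5, listed at 0 in the control, stood at 2.03 ± 1.64 FPKM. Among the 60 xenobiotic cytochrome P450 genes, 58 rose, 1 fell and 1 was not called (median 2.57, camera adjusted p = 2.7e-11, adjusted p = 0.26 with an estimated correlation). The genes cyp-35B2 and cyp-35A1 rose by 6.88 ± 0.14 and 6.66 ± 0.10. Among the 29 PMK-1 innate immunity genes, 26 rose, 2 fell and 1 was not called (median 1.31, camera adjusted p = 8.4e-04, adjusted p = 0.26 with an estimated correlation). Among the 37 intracellular pathogen response genes, 31 rose, 2 fell and 4 were not called (median 1.2, camera adjusted p = 0.0012, adjusted p = 0.32 with an estimated correlation). Among the 59 neuropeptide genes, 47 rose, 4 fell and 8 were not called (median 0.74, camera adjusted p = 0.0020, adjusted p = 0.61 with an estimated correlation).

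Among the 137 cuticle collagen genes, 94 fell, 30 rose and 13 were not called (median -2.67, camera adjusted p = 3.6e-13, adjusted p = 0.081 with an estimated correlation). Among the 53 moulting and apical matrix genes, 42 fell, 8 rose and 3 were not called (median -2.63, camera adjusted p = 5.5e-12, adjusted p = 0.26 with an estimated correlation). Among the 45 muscle genes, 39 fell, 2 rose and 4 were not called (median -1.11, camera adjusted p = 4.7e-13, adjusted p = 0.26 with an estimated correlation). The troponin genes tni-3, mup-2 and tni-1 changed by -2.86, -2.76 and -2.7. Among the 52 nuclear oxidative phosphorylation genes, 47 fell, 4 rose and 1 was not called (median -0.96, camera adjusted p = 3.6e-13, adjusted p = 0.058 with an estimated correlation). Against the direction of that list, the cytochrome c gene cyc-2.2 rose by 3.36. Of 53 neuronal genes, 28 fell, 14 rose and 11 were not called (median -0.28, camera adjusted p = 0.0021, adjusted p = 0.44 with an estimated correlation). The touch neuron genes mec-7, mec-12 and mec-17 changed by -2.52, -2.28 and -1.94. The DNA replication and cell cycle list was not called, with 32 genes risen and 20 fallen of 60 (camera adjusted p = 0.70). Of the called genes 65% were higher as deposited, 50.9% under median-of-ratios scaling and 53.7% under quantile normalization, and the median of all genes moved from 0.30 to 0.03 and 0.07.

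After 48 h of rps-11 RNAi pathogen response, innate immunity and large-subunit ribosomal protein genes were higher than in the 24 h control, nuclear genes of oxidative phosphorylation were lower, and genes of fatty acid breakdown were among the largest falls. Camera called 21 of 40 lists at its preset correlation, 1 with an estimated one (5 at an unadjusted p under 0.05), and fry called 37. The acyl-CoA dehydrogenase gene acdh-1 (chromosome I, 6497436 to 6499560, build ce11), of the propionate shunt, changed from 305 ± 41.1 to 0.522 ± 0.385 FPKM, by -7.68 ± 0.23 on the log2 scale (limma adjusted p = 1.2e-13). The acyl-CoA oxidase gene acox-1.2 changed by -6.18 ± 0.12 and the lipase gene lips-6 by -6.53 ± 0.14. The gene B0563.9 rose by 8.73 ± 0.22, the F-box gene fbxa-163 by 7.05 ± 0.08 and the P-glycoprotein gene pgp-8 by 6.32 ± 0.09. Among genes that led at 48 h of egl-45 RNAi, tbb-6 rose by 5.28 ± 0.05, to 145 ± 4.79 FPKM, ilys-3 by 5.83 ± 0.16 and irg-5 by 3.8 ± 0.13. In all, 10960 genes were called, 6727 higher and 4233 lower, with 2340 higher and 1438 lower by at least 2-fold.

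Across 37 intracellular pathogen response genes, 31 rose, 1 fell and 5 were not called (median 1.53, camera adjusted p = 5.2e-06, adjusted p = 0.34 with an estimated correlation). The genes pals-26 and pals-6 rose by 3.46 and 3.41. Among the 48 epidermal antimicrobial peptide genes, 35 rose, 4 fell and 9 were not called (median 1.26, 35 risen and 5 fallen adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.70 with an estimated correlation). The fungus-induced protein gene fipr-24 rose by 5.81 ± 0.16. Across 29 PMK-1 innate immunity genes, 20 rose, 5 fell and 4 were not called (median 0.67, camera adjusted p = 0.016, adjusted p = 0.50 with an estimated correlation). Among the 26 DAF-16 activated genes, 19 rose, 7 fell and 0 were not called (median 1.19, camera adjusted p = 0.025, adjusted p = 0.34 with an estimated correlation). The small heat shock gene hsp-12.6 rose by 4.5 and mtl-1 by 5.66. Across 59 neuropeptide genes, 57 rose, 1 fell and 1 was not called (median 1.08, camera adjusted p = 1.2e-08, adjusted p = 0.42 with an estimated correlation). Among the 46 large-subunit ribosomal protein genes, 31 rose, 2 fell and 13 were not called (median 0.50, camera adjusted p = 0.0044, adjusted p = 0.78 with an estimated correlation). The median was 0.24 under median-of-ratios scaling and 0.30 under quantile normalization. Here rla-0 rose by 1.57 ± 0.07 and rpl-11.1 by 1.32.

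Across 52 nuclear oxidative phosphorylation genes, 49 fell, 0 rose and 3 were not called (median -0.88, camera adjusted p = 2.8e-15, adjusted p = 0.032 with an estimated correlation). It was the 1 list of this comparison that held its call with an estimated correlation, and cox-17, ucr-11 and hpo-18 changed by -2.03, -2.02 and -2.01. Among the 39 proteasome genes, 31 fell, 4 rose and 4 were not called (median -0.64, camera adjusted p = 4.6e-08, adjusted p = 0.34 with an estimated correlation). Across 45 muscle genes, 36 fell, 3 rose and 6 were not called (median -0.58, camera adjusted p = 2.7e-09, adjusted p = 0.34 with an estimated correlation). Of 31 aminoacyl-tRNA synthetase genes, 24 fell, 2 rose and 5 were not called (median -0.33, camera adjusted p = 6.1e-05, adjusted p = 0.59 with an estimated correlation). Across 53 moulting and apical matrix genes, 33 fell, 12 rose and 8 were not called (median -0.93, camera adjusted p = 6.8e-06, adjusted p = 0.42 with an estimated correlation). Across 137 cuticle collagen genes, 74 fell, 41 rose and 22 were not called (median -0.59, camera adjusted p = 0.0013, adjusted p = 0.43 with an estimated correlation). Of 40 lipolysis and fatty acid oxidation genes, 21 fell, 15 rose and 4 were not called (median -0.50, 15 risen and 23 fallen adjusted over the list alone, camera adjusted p = 0.021, adjusted p = 0.68 with an estimated correlation). That call was lost under both other scalings (camera adjusted p = 0.085 and 0.083), and the acyl-CoA synthetase gene acs-2 rose by 5.33 ± 0.17. Of the called genes 61.4% were higher as deposited, 47.8% under median-of-ratios scaling and 49.5% under quantile normalization, and the median of all genes moved from 0.18 to 0.001 and -0.001.

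After 120 h of rps-11 RNAi, sperm and germline genes were higher than in the 24 h control, and single collagen genes were among the largest rises. Of 40 lists, camera called 19 at its preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05), and fry called 33. The adult-specific collagen gene col-19 (chromosome X, 421707 to 422691, build ce11) stood at 0.0143 ± 0.0248 FPKM in the control and at 369 ± 96.8 in these libraries, a log2 change of 8.48 ± 0.16 (limma adjusted p = 9.6e-16). Other collagen genes, col-140, col-122, col-124 and col-181, rose by 9.01, 9.0, 8.87 and 8.84. The sperm gene msp-57, listed at 0 in the control, stood at 146 ± 19.9 FPKM, and the yolk protein genes vit-2 and vit-6 rose by 5.06 ± 0.24 and 5.11 ± 0.21. The log2 change was -7.85 ± 0.23 for acdh-1 and -6.87 ± 0.12 for acox-1.2, while B0563.9 rose by 9.28 ± 0.22, ilys-3 by 7.6 ± 0.16 and tbb-6 by 5.55 ± 0.05. In all, 12126 genes were called, 7612 higher and 4514 lower, with 3797 higher and 1817 lower by at least 2-fold.

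Among the 41 sperm genes, 41 rose, 0 fell and 0 were not called (median 5.7, camera adjusted p = 3.6e-12, adjusted p = 0.48 with an estimated correlation). Over the 19 members not listed at 0 in the control the median was 5.01. Among the 53 germline genes, 50 rose, 1 fell and 2 were not called (median 1.6, camera adjusted p = 9.2e-08, adjusted p = 0.59 with an estimated correlation). The oocyte RNA-binding protein genes pos-1, puf-5 and mex-5 rose by 3.61, 3.41 and 3.24. The cuticle collagen list was split, with 60 genes risen and 71 fallen of 137, and was not called (camera adjusted p = 0.12). Of 37 intracellular pathogen response genes, 33 rose, 0 fell and 4 were not called (median 2.2, 33 risen and 2 fallen adjusted over the list alone, camera adjusted p = 4.6e-06, adjusted p = 0.36 with an estimated correlation). The genes pals-14 and eol-1 rose by 4.58 and 4.17. Across 48 epidermal antimicrobial peptide genes, 38 rose, 4 fell and 6 were not called (median 1.88, camera adjusted p = 0.0060, adjusted p = 0.70 with an estimated correlation). The caenacin gene cnc-6 rose by 5.33. The PMK-1 innate immunity list was not called, 14 genes having risen and 12 fallen of 29 (camera adjusted p = 0.47). Across 46 large-subunit ribosomal protein genes, 37 rose, 1 fell and 8 were not called (median 0.60, camera adjusted p = 0.012, adjusted p = 0.77 with an estimated correlation). Under median-of-ratios scaling that median was 0.29 (camera adjusted p = 0.050), and under quantile normalization 0.27.

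Of 45 muscle genes, 42 fell, 1 rose and 2 were not called (median -1.26, camera adjusted p = 3.0e-13, adjusted p = 0.36 with an estimated correlation). The muscle gene dim-1 changed by -2.45. Of 52 nuclear oxidative phosphorylation genes, 46 fell, 6 rose and 0 were not called (median -1.04, camera adjusted p = 4.7e-12, adjusted p = 0.083 with an estimated correlation). Again cyc-2.2 rose, by 4.9. Of 53 moulting and apical matrix genes, 39 fell, 10 rose and 4 were not called (median -1.35, camera adjusted p = 7.1e-08, adjusted p = 0.48 with an estimated correlation). Of 44 intestinal genes, 27 fell, 11 rose and 6 were not called (median -0.58, camera adjusted p = 6.1e-05, adjusted p = 0.48 with an estimated correlation). The aspartyl protease gene asp-13 changed by -3.12 and the peptide transporter gene pept-1 by -2.34. Of 194 nuclear hormone receptor genes, 135 rose, 28 fell and 31 were not called (median 0.47, camera adjusted p = 0.026, adjusted p = 0.59 with an estimated correlation). Under quantile normalization their median was -0.01 and the call was lost (camera adjusted p = 0.72), as it was with no filter on low values (0.10). Of the called genes 62.8% were higher as deposited, 50.2% under median-of-ratios scaling and 47.3% under quantile normalization, and the median of all genes moved from 0.28 to 0.01 and -0.07.

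**Figure D3:**
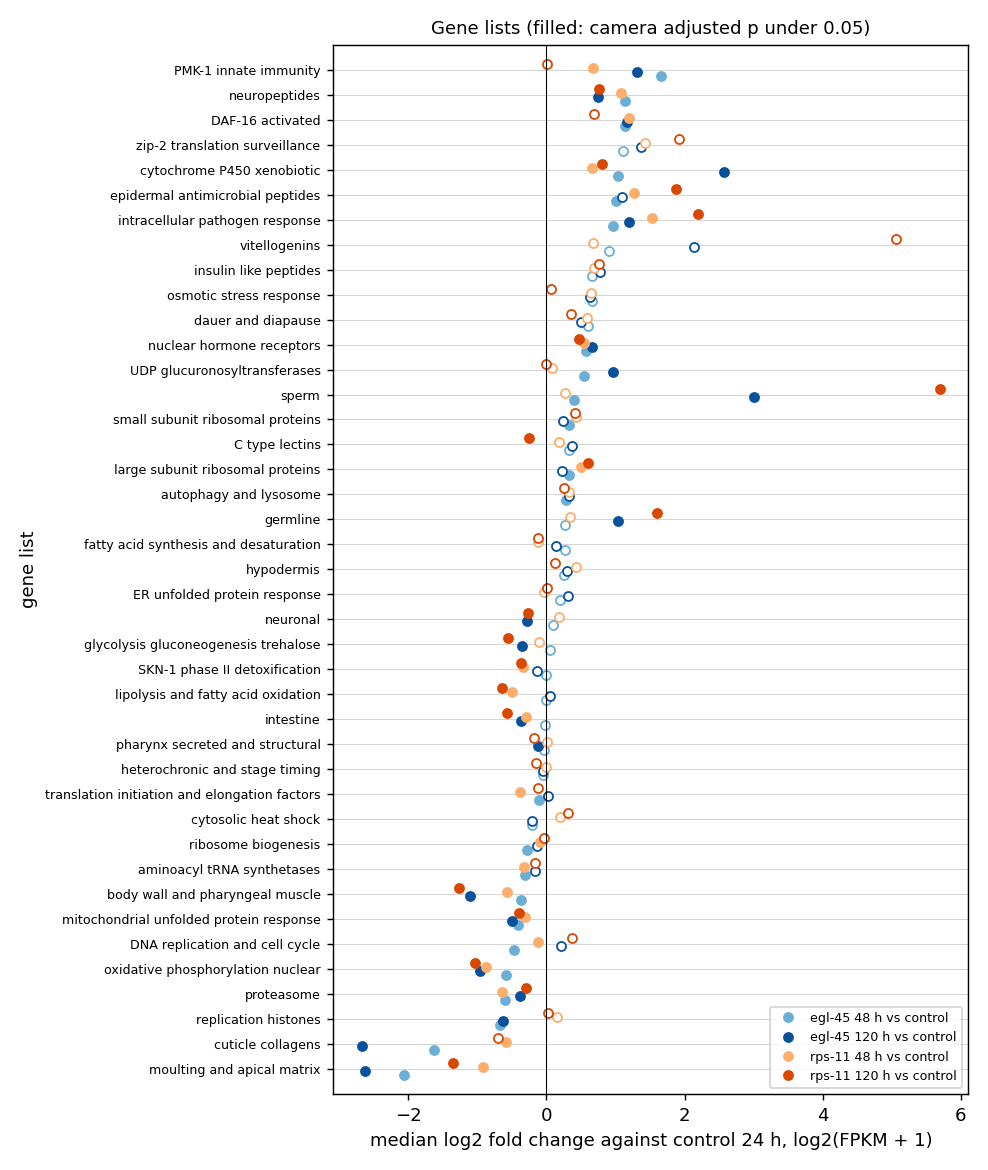
Median log2 change of each gene list against the 24 h control on the log2(FPKM + 1) scale (x axis), 1 line per list and 1 color per RNAi group, filled where camera passed an adjusted p of 0.05 and open where it did not or, for the vitellogenins, was not run. The sperm list lies at 5.7 after 120 h of rps-11 RNAi and at 0.26 after 48 h, and the cuticle collagens lie between -2.67 and -0.59.

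**Figure D4:**
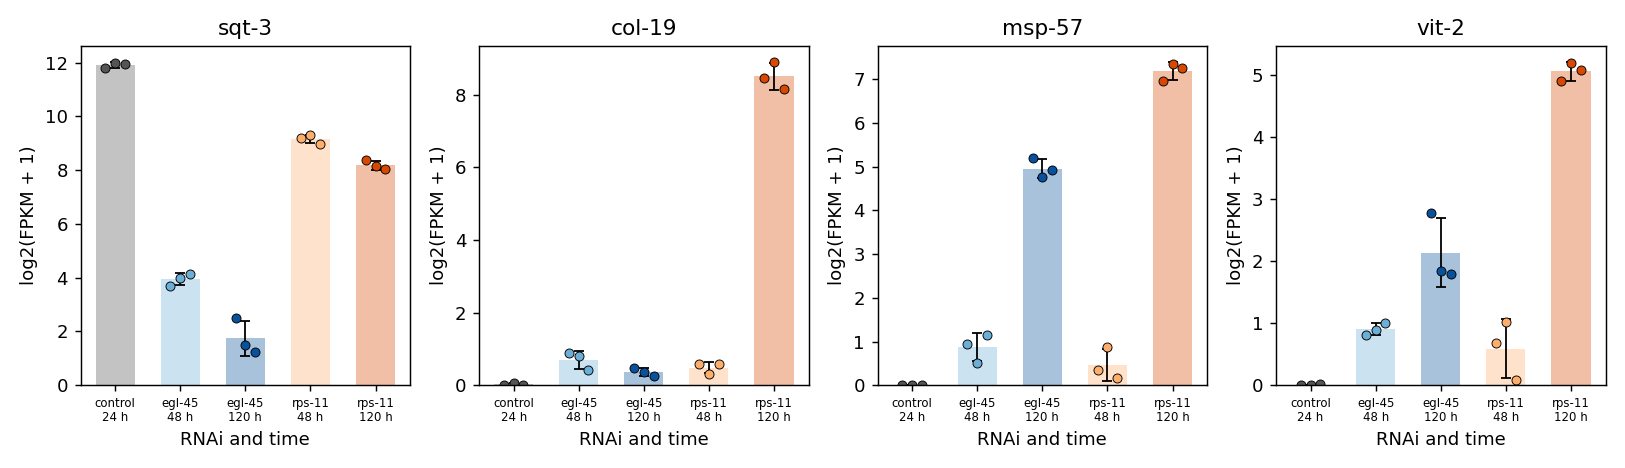
log2(FPKM + 1) of the larval collagen gene sqt-3, the adult collagen gene col-19, the sperm gene msp-57 and the yolk gene vit-2 in the 5 groups, with bars for the mean of 3 libraries, error bars for the SD and points for libraries. The col-19 transcript stands at 369 FPKM under rps-11 RNAi at 120 h and under 1 FPKM on average in every other group.

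The comparisons with the control moved many genes the same way. In all 4, 4506 genes rose and 2727 fell, 1306 and 934 of them by at least 2-fold each time. The smallest of the 4 log2 changes was 8.13 for B0563.9, 6.48 for T26H5.9, 6.15 for Y68A4A.13, 5.83 for ilys-3, 5.66 for mtl-1 and 5.28 for tbb-6, and acdh-1, lips-6 and acox-1.2 fell each time. Independent lists of these sizes would share 834 risen and 107 fallen genes, and unchanged groups simulated against the same control libraries (20 simulations) shared 0. With no change simulated, few genes can be called. That 0 is therefore no chance level for groups in which most genes were called. Log2 changes of pairs of comparisons correlated across genes at 0.70 to 0.90, against 0.49 to 0.50 for the simulated groups, with covariances of 1.3 to 1.91 against 0.0072 to 0.0073. These simulations hold the spread between the shared control libraries, which therefore gives only covariances of that small size. Any trait of the control group as a whole, such as its earlier time of 24 h, enters all 4 comparisons. It may give part of the excess and was not measured. Since 3 control libraries cannot be split into parts of at least 2, the comparisons were not repeated against separate control libraries.

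Between 48 h and 120 h of egl-45 RNAi, genes of the germline and of cell division rose and genes of muscle, neurons and intestine fell. Camera called 23 of 40 lists at its preset correlation, 0 with an estimated one (6 at an unadjusted p under 0.05), and fry called 29. The gene H25K10.4 rose from 1.6 ± 0.434 to 106 ± 7.37 FPKM, by 5.37 ± 0.14 on the log2 scale (limma adjusted p = 2.2e-12), and col-143 and the glucuronosyltransferase gene ugt-37 rose by 5.16 ± 0.16 and 4.8 ± 0.21. The pud genes pud-3, pud-4 and pud-1.2 changed by -6.79 ± 0.27, -5.52 ± 0.22 and -4.64 ± 0.22, and the lysozyme gene ilys-5 by -3.65 ± 0.09. Values of pud genes are uncertain where a near-identical copy exists, and which of them have one was not examined. The targeted gene egl-45 rose by 0.52 ± 0.07 (limma adjusted p = 1.1e-05). Across 41 sperm genes, 41 rose, 0 fell and 0 were not called (median 2.53, camera adjusted p = 4.3e-17, adjusted p = 0.23 with an estimated correlation). Across 53 germline genes, 52 rose, 0 fell and 1 was not called (median 0.95, camera adjusted p = 2.9e-13, adjusted p = 0.36 with an estimated correlation). Among the 60 DNA replication and cell cycle genes, 54 rose, 2 fell and 4 were not called (median 0.61, 55 risen and 2 fallen adjusted over the list alone, camera adjusted p = 2.6e-09, adjusted p = 0.38 with an estimated correlation). The cell cycle genes cdk-2 and bub-1 rose by 1.44 and 1.29. Across 60 xenobiotic cytochrome P450 genes, 52 rose, 3 fell and 5 were not called (median 1.25, 52 risen and 4 fallen adjusted over the list alone, camera adjusted p = 4.1e-12, adjusted p = 0.29 with an estimated correlation). The largest rise in that list was that of cyp-14A3, 4.01 ± 0.13.

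Among the 45 muscle genes, 38 fell, 2 rose and 5 were not called (median -0.66, camera adjusted p = 1.3e-15, adjusted p = 0.23 with an estimated correlation). Among the 53 neuronal genes, 36 fell, 5 rose and 12 were not called (median -0.35, camera adjusted p = 6.2e-09, adjusted p = 0.23 with an estimated correlation). Of 59 neuropeptide genes, 33 fell, 1 rose and 25 were not called (median -0.28, camera adjusted p = 6.8e-07, adjusted p = 0.41 with an estimated correlation). Among the 44 intestinal genes, 28 fell, 6 rose and 10 were not called (median -0.41, camera adjusted p = 3.8e-07, adjusted p = 0.23 with an estimated correlation). The intermediate filament gene ifc-1 changed by -2.17. Of 137 cuticle collagen genes, 64 fell, 19 rose and 54 were not called (median -0.37, camera adjusted p = 7.4e-08, adjusted p = 0.23 with an estimated correlation). Of 9066 called genes 5754 rose and 3312 fell with time (1213 and 487 by at least 2-fold). The risen made 63.5% as deposited, 51.4% under median-of-ratios scaling and 49.7% under quantile normalization.

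Between 48 h and 120 h of rps-11 RNAi, sperm and germline genes rose, and neuronal and muscle genes fell. Of 40 lists, camera called 22 at its preset correlation and 0 with an estimated one (6 at an unadjusted p under 0.05), and fry called 33. The collagen gene col-124 rose by 8.58 ± 0.15, from 0.854 ± 0.289 to 719 ± 186 FPKM, col-19 by 8.02 ± 0.16 (limma adjusted p = 1.2e-14) and col-119 by 7.5 ± 0.20. The list of 137 cuticle collagen genes was not called, with 54 risen and 46 fallen (median 0.02, 54 risen and 47 fallen adjusted over the list alone, camera adjusted p = 0.26), although under quantile normalization it passed the test as higher with a median of -0.19 (camera adjusted p = 0.024). The log2 change was -3.91 ± 0.16 for the lectin gene clec-45, -2.98 ± 0.14 for dod-22, -2.77 ± 0.14 for the tubulin gene tba-8 and -2.7 ± 0.13 for irg-5. Of 41 sperm genes, 41 rose, 0 fell and 0 were not called (median 5.46, camera adjusted p = 2.3e-24, adjusted p = 0.16 with an estimated correlation). Of 53 germline genes, 52 rose, 0 fell and 1 was not called (median 1.16, camera adjusted p = 2.6e-15, adjusted p = 0.32 with an estimated correlation). The yolk protein genes vit-2, vit-6 and vit-5 rose by 4.47, 4.34 and 1.95. Across 60 DNA replication and cell cycle genes, 55 rose, 2 fell and 3 were not called (median 0.59, camera adjusted p = 4.1e-09, adjusted p = 0.37 with an estimated correlation). Across 39 proteasome genes, 34 rose, 0 fell and 5 were not called (median 0.27, camera adjusted p = 7.4e-05, adjusted p = 0.37 with an estimated correlation). Among the 37 intracellular pathogen response genes, 25 rose, 1 fell and 11 were not called (median 0.34, camera adjusted p = 0.0016, adjusted p = 0.37 with an estimated correlation). Of 29 PMK-1 innate immunity genes, 20 fell, 4 rose and 5 were not called (median -0.71, camera adjusted p = 4.8e-06, adjusted p = 0.18 with an estimated correlation). Across 53 neuronal genes, 43 fell, 1 rose and 9 were not called (median -0.59, camera adjusted p = 4.2e-12, adjusted p = 0.16 with an estimated correlation). Across 45 muscle genes, 38 fell, 2 rose and 5 were not called (median -0.43, camera adjusted p = 1.4e-09, adjusted p = 0.32 with an estimated correlation). Of 9830 called genes 5580 rose and 4250 fell with time (1500 and 356 by at least 2-fold). The risen made 56.8% as deposited, 52.5% under median-of-ratios scaling and 41.5% under quantile normalization.

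At 48 h cuticle and moulting genes were higher under rps-11 than under egl-45 RNAi, and innate immunity, cytochrome P450 and glucuronosyltransferase genes were lower. Camera called 23 of 40 lists at its preset correlation, 0 with an estimated one (8 at an unadjusted p under 0.05), and fry called 30. Under rps-11 RNAi col-73 stood at 488 ± 108 FPKM, against 8.62 ± 4.54 under egl-45 RNAi, a log2 difference of 5.78 ± 0.35 (limma adjusted p = 2.7e-09), and sqt-1 was higher by 5.66 ± 0.19. The genes pud-3, sysm-1 and dod-21 were lower, with log2 differences of -6.99 ± 0.27, -5.87 ± 0.20 and -4.62 ± 0.11. Among the 137 cuticle collagen genes, 94 were higher, 9 were lower and 34 were not called (median 1.02, 97 higher and 9 lower adjusted over the list alone, camera adjusted p = 1.3e-17, adjusted p = 0.053 with an estimated correlation). Among the 53 moulting and apical matrix genes, 43 were higher, 3 were lower and 7 were not called (median 1.34, 44 higher and 3 lower adjusted over the list alone, camera adjusted p = 2.6e-14, adjusted p = 0.091 with an estimated correlation). Among the 29 PMK-1 innate immunity genes, 20 were lower, 5 were higher and 4 were not called (median -0.92, 6 higher and 20 lower adjusted over the list alone, camera adjusted p = 2.4e-09, adjusted p = 0.053 with an estimated correlation). Of 58 glucuronosyltransferase genes, 39 were lower, 8 were higher and 11 were not called (median -0.49, camera adjusted p = 1.1e-09, adjusted p = 0.053 with an estimated correlation). Of 60 xenobiotic cytochrome P450 genes, 36 were lower, 4 were higher and 20 were not called (median -0.45, camera adjusted p = 2.0e-08, adjusted p = 0.30 with an estimated correlation). Of 26 replication histone genes, 16 were higher, 1 was lower and 9 were not called (median 0.61, camera adjusted p = 5.7e-05, adjusted p = 0.053 with an estimated correlation). Among the 40 lipolysis and fatty acid oxidation genes, 27 were lower, 4 were higher and 9 were not called (median -0.41, camera adjusted p = 3.6e-08, adjusted p = 0.18 with an estimated correlation). Among the 52 nuclear oxidative phosphorylation genes, 30 were lower, 1 was higher and 21 were not called (median -0.26, camera adjusted p = 1.0e-07, adjusted p = 0.078 with an estimated correlation). Of 6516 called genes 3573 were higher and 2943 lower under rps-11 RNAi (708 and 321 by at least 2-fold). The higher made 54.8% as deposited, 47.2% under median-of-ratios scaling and 44.9% under quantile normalization.

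At 120 h collagen, sperm and yolk protein genes were higher under rps-11 than under egl-45 RNAi, and cytochrome P450 and glucuronosyltransferase genes were lower. Of 40 lists, camera called 20 at its preset correlation and 3 with an estimated one (7 at an unadjusted p under 0.05), and fry called 27. The collagen genes col-20, col-93, col-124 and col-19 were higher under rps-11 RNAi by 8.51, 8.33, 8.15 and 8.14 (limma adjusted p = 1.6e-15, 1.3e-13, 3.2e-15 and 7.3e-15). The infection response gene irg-5 stood at 17 ± 2.9 FPKM, against 1399 ± 59.4 under egl-45 RNAi, a log2 difference of -6.29 ± 0.13. The differences were -6.03 ± 0.13 for comt-4, -5.37 ± 0.14 for cyp-35B2 and -5.36 ± 0.20 for sysm-1. Across 137 cuticle collagen genes, 124 were higher, 5 were lower and 8 were not called (median 3.14, 125 higher and 5 lower adjusted over the list alone, camera adjusted p = 4.2e-32, adjusted p = 0.0069 with an estimated correlation). Among the 58 glucuronosyltransferase genes, 44 were lower, 6 were higher and 8 were not called (median -0.79, camera adjusted p = 6.3e-11, adjusted p = 0.048 with an estimated correlation). Across 26 DAF-16 activated genes, 20 were lower, 4 were higher and 2 were not called (median -0.82, 4 higher and 21 lower adjusted over the list alone, camera adjusted p = 7.8e-06, adjusted p = 0.025 with an estimated correlation). These 3 lists held their calls with an estimated correlation. Among the 60 xenobiotic cytochrome P450 genes, 57 were lower, 1 was higher and 2 were not called (median -1.63, camera adjusted p = 1.3e-23, adjusted p = 0.082 with an estimated correlation). Across 29 PMK-1 innate immunity genes, 22 were lower, 3 were higher and 4 were not called (median -1.09, 3 higher and 23 lower adjusted over the list alone, camera adjusted p = 1.8e-08, adjusted p = 0.064 with an estimated correlation). Among the 41 sperm genes, 39 were higher, 0 were lower and 2 were not called (median 2.54, camera adjusted p = 6.9e-18, adjusted p = 0.16 with an estimated correlation). The yolk protein genes vit-2, vit-6 and vit-5 were higher by 2.92, 2.65 and 1.16. Of 8831 called genes 4650 were higher and 4181 lower under rps-11 RNAi (1495 and 634 by at least 2-fold). The higher made 52.7% as deposited, 54.9% under median-of-ratios scaling and 41.04% under quantile normalization.

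The change from 48 h to 120 h differed between the RNAi treatments for 5155 genes, 2561 with a more positive change under rps-11 RNAi and 2594 with a more negative one (880 and 371 by at least 2-fold). The more positive made 49.7% as deposited, 59.5% under median-of-ratios scaling and 40.4% under quantile normalization. The difference of changes was 8.35 ± 0.23 for col-19 (limma adjusted p = 1.5e-12) and 8.26 ± 0.21 for col-124. It was -3.93 ± 0.20 for H25K10.4 and -3.32 ± 0.29 for ugt-37, genes that rose with time under egl-45 RNAi. In the lists that follow, higher means a more positive change under rps-11 RNAi. Camera called 12 of 40 lists at its preset correlation, 0 with an estimated one (6 at an unadjusted p under 0.05), and fry called 16. Across 41 sperm genes, 38 were higher, 0 were lower and 3 were not called (median 2.72, camera adjusted p = 3.1e-29, adjusted p = 0.10 with an estimated correlation). Of 137 cuticle collagen genes, 83 were higher, 8 were lower and 46 were not called (median 1.03, 88 higher and 11 lower adjusted over the list alone, camera adjusted p = 3.2e-18, adjusted p = 0.061 with an estimated correlation). Across 60 xenobiotic cytochrome P450 genes, 51 were lower, 0 were higher and 9 were not called (median -1.1, 1 higher and 51 lower adjusted over the list alone, camera adjusted p = 9.6e-23, adjusted p = 0.11 with an estimated correlation). Among the 194 nuclear hormone receptor genes, 72 were lower, 9 were higher and 113 were not called (median -0.23, 9 higher and 73 lower adjusted over the list alone, camera adjusted p = 2.4e-05, adjusted p = 0.25 with an estimated correlation). Of 26 DAF-16 activated genes, 16 were lower, 2 were higher and 8 were not called (median -0.38, camera adjusted p = 3.1e-04, adjusted p = 0.076 with an estimated correlation). Across 52 nuclear oxidative phosphorylation genes, 22 were higher, 1 was lower and 29 were not called (median 0.21, 24 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.1e-04, adjusted p = 0.26 with an estimated correlation). In the 5 comparisons among RNAi groups, too, counts adjusted over the list alone equal those over all genes unless another is given.

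Values of multigene families such as the collagen, msp, pals, fipr and histone genes are uncertain where the authors' counting could split reads between near-identical copies, and those of overlapping or antisense genes likewise, since the use of strand in the counting is not stated. In the authors' deposited table for egl-45 RNAi at 48 h, 10412 genes passed an adjusted p of 0.05, of which 9812 were among the genes tested with limma and 8850 also called by it, all in the same direction. For egl-45 RNAi at 120 h, 12112 genes passed in the authors' deposited table, 10917 of them tested with limma, 9684 also called by it and 9665 of those in the same direction. For rps-11 RNAi at 48 h, 10002 genes passed in the authors' deposited table, 9362 of them tested with limma and 8681 also called by it, all in the same direction. For rps-11 RNAi at 120 h, 12443 genes passed in the authors' deposited table, 10915 of them tested with limma and 10089 also called by it, all in the same direction. The authors' deposited table gave log2 changes of 7.63 for tbb-6 and -8.72 for acdh-1 at 48 h of egl-45 RNAi and of 14.38 for col-19 at 120 h of rps-11 RNAi. Across genes, log2 changes in the authors' deposited tables correlated with those of limma at 0.93 to 0.94. A correlation does not show a constant shift. The median difference of the authors' log2 changes from those of limma was -0.18 and -0.32 for egl-45 RNAi at 48 h and 120 h. For rps-11 RNAi it was -0.22 and -0.27. In the same order the authors' deposited tables called 5124, 6422, 4937 and 6889 genes higher and 5288, 5690, 5065 and 5554 lower. The excess of risen genes in limma was thus smaller or absent there.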

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

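All tests in this part were chosen after the results were seen, except the counts over other splits of the libraries and the test of a difference in change between the RNAi treatments, which were planned. With 3 libraries per group, single libraries were not examined for extreme values.

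The planned test of whether the change from 48 h to 120 h differs between rps-11 and egl-45 RNAi called 5155 genes and 12 gene lists, which is why these results are given here. The most positive differences of log2 change were those of col-19 (8.35), col-124 (8.26), col-178 (7.72), col-20 (7.56) and col-139 (7.54), all of them collagen genes. The most negative were those of H25K10.4 (-3.93), ugt-37 (-3.32), Y73C8C.10 (-3.3), cyp-14A4 (-3.07) and cyp-14A3 (-3.07). Of 100 drawn from the 200 splits that exchange libraries between the times of a treatment, 3 gave as many genes, the real one included, under a share of 0.05. The split that fully exchanges the times of rps-11 RNAi was not among those drawn. The highest count of another split was 5829, more than the real 5155. Both other splits kept the times of rps-11 RNAi apart while mixing those of egl-45 RNAi. The count of a mixed split thus carries the time effect of 1 treatment. Such splits do not stand for an equal change in both treatments, and they cannot decide whether the changes differ.

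Sperm and yolk protein transcripts and that of the adult collagen gene col-19 stood higher in the rps-11 RNAi 120 h libraries than in every other group, although the submitters describe all RNAi animals as arrested in the L2 stage. Scaling between libraries is argued against as the whole cause, since the mean log2 change of the 41 tested sperm genes was 5.41 (SE 0.034) as deposited and 5.3 (SE 0.025) after median-of-ratios scaling. An exchange with control or egl-45 RNAi libraries is argued against by the target, whose highest level among the 3 libraries was 35.39% of the control mean, and one of some libraries between the times of rps-11 RNAi by the sperm genes, whose lowest mean at 120 h lay 4.87 above the highest at 48 h on the log2 scale, but an exchange of all 3 was not tested. A candidate explanation that stays open is that some animals in these pools were past the arrest. The spread of the sperm genes' deviations between the 3 libraries lay at the 98.4 percentile of 10000 random lists, and that of 45 cuticle collagens, picked for a called log2(FPKM + 1) difference of at least 1 in these libraries from the control and from egl-45 RNAi at 120 h, at the 100 percentile. The random lists were matched by level alone. Genes that vary together would lie high among them with or without such animals, so these percentiles cannot decide it. Sperm genes and these collagens deviated the same way in replicates 1 (-0.06 and -0.13 on the log2 scale) and 2 (0.05 and 0.16) and not in replicate 3 (0.01 and -0.03). That leaves open both animals past the arrest and a change of these transcripts in animals that stayed arrested. Late transcripts were not confined to rps-11 RNAi. At 120 h of egl-45 RNAi msp-57 stood at 26.1 to 35.5 FPKM and vit-6 at 4.12 to 8.58. There col-19 stood at 0.19 to 0.38 FPKM, while the collagen gene col-140 stood at 100.19, against 0.547 in the control. Animals past the arrest were not tested for in the egl-45 RNAi libraries.

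Large-subunit ribosomal protein genes stood higher under rps-11 RNAi than in the control, while rps-11 itself was lower. A positive median was not particular to the large subunit. As deposited, the median log2 change of the 32 small-subunit genes was 0.43 at 48 h and 0.42 at 120 h. That of the 46 large-subunit genes was 0.50 and 0.60. The values that follow are of the large-subunit genes. The size of this depends on the scaling between libraries. The mean log2 change at 120 h was 0.58 as deposited and 0.28 (SE 0.10) after median-of-ratios scaling, and at 48 h 0.50 and 0.25 (SE 0.11). After quantile normalization it was 0.40 (SE 0.0074) at 120 h and 0.36 (SE 0.012) at 48 h. The mean stayed above 0 each time. With 3 libraries per group and the SEs after median-of-ratios scaling, scaling as the whole cause is not excluded. Under egl-45 RNAi at 120 h median-of-ratios scaling moved the mean of these genes from 0.27 to -0.05, while quantile normalization left it at 0.28. Whether a few abundant genes that fill the libraries are a source stays open: scaling without the 100 most abundant genes of each library gave 0.70 (SE 0.09), but 44 of the 46 large-subunit genes were among those, and their share of all FPKM, 40.7% in the control and 47.4% at 120 h, fixed the direction. A response to the loss of a ribosomal protein was not tested.

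Cuticle collagen and moulting genes stood higher under rps-11 than under egl-45 RNAi at 48 h. Scaling is argued against as the whole cause, since the mean log2 difference over 190 genes was 1.62 as deposited and 1.58 (SE 0.04) after median-of-ratios scaling. Animals like the 24 h control mixed into the rps-11 pools could give such a difference, and a milder effect of rps-11 RNAi was not tested. A share of 12.1% of the control level, the median of 17 moulting genes, would be needed. Of 198 other genes at least 16-fold lower under egl-45 RNAi, 22 (11.11%) lay more than 4-fold below the level this share gives. The median share of the 198 genes was 10.03%, and their bulk does not decide it. A mixture would, however, hold every gene at or above its share of the control level. Among the 22 genes, acdh-1 stood at 0.522 ± 0.385 FPKM at 48 h of rps-11 RNAi, against 305 ± 41.1 in the control. For acox-1.2 the values were 7.79 ± 1.02 and 635 ± 58 FPKM. These 22 genes, picked by their low values, argue against animals that match the 24 h control in every gene as the whole cause of the difference. A mixture with animals that differ from the control in these genes is not excluded.

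The planned counts over other splits used 10 splits of 6 libraries for each of the other 8 contrasts, too few for a share under 0.05. In each the real split gave the highest count, 1 of 10, and the highest of the other splits was 0, against real counts of 10526, 11938, 10960 and 12126 for the comparisons with the control, 9066 and 9830 between the times and 6516 and 8831 between the treatments. For genes called the same way in all 4 comparisons with the control, 7233 in the real grouping, 1 of 100 splits gave as many, the real one, and the highest of the others was 0, so a random regrouping is excluded as the source at a share of 0.05. Mixed groups have a wider spread, so this says that the groups differ and nothing of the size of the overlap.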

How the results depend on the processing

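The fit without the rps-11 RNAi 120 h libraries was chosen after seeing the data, and all other alternatives were planned. The counts of called genes stayed within 1.5 times their value in every setting. Leaving out single libraries aside, they ranged from 8411 to 11257 for egl-45 RNAi at 48 h against the control, 9085 to 13693 at 120 h, 8653 to 12017 for rps-11 RNAi at 48 h and 9212 to 14324 at 120 h. Counts from 48 h to 120 h ranged from 7171 to 10010 (egl-45) and 7514 to 11282 (rps-11), between treatments from 5479 to 6621 at 48 h and 6682 to 10439 at 120 h, for the difference in change from 3758 to 6016, and for genes called in all 4 comparisons with the control the same way from 5839 to 7513. Without the rps-11 RNAi 120 h libraries, 10556, 11991 and 10999 genes were called against the control, 9106 between the times of egl-45 RNAi, 6533 between the treatments at 48 h, and 7922 the same way in the 3 comparisons left. These totals hide a turnover of genes. Of the genes called as deposited, 86% to 98% per contrast were also called under median-of-ratios scaling and 81.1% to 93.9% under quantile normalization. In the comparisons with the control, in the order above, 3, 102, 9 and 64 of the genes called both times turned direction under median-of-ratios scaling. Under quantile normalization 8, 21, 21 and 324 did.

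With the correlation estimated per list, the number of called lists went from 23, 20, 21 and 19 to 0, 0, 1 and 0 in the comparisons with the control, from 23 and 22 to 0 and 0 between the times, from 23 and 20 to 0 and 3 between the treatments, and from 12 to 0 for the difference in change. By its construction this setting widens the error of lists whose members vary together among libraries. At an unadjusted p of 0.05 it called 8, 6, 5, 3, 6, 6, 8, 7 and 6 lists in that order. With fry, which compares a list with no other genes, 38, 37, 37 and 33 lists were called in the comparisons with the control. Of 183 called list results, 11 lost their call under median-of-ratios scaling, 30 under quantile normalization, 15 at a mean FPKM of at least 5, 6 with only the groups compared, 5 and 3 with pseudocounts of 5 and 0.1, 3 with no filter, 4 with fry and 4 with the replicate block. The C-type lectin list at 120 h of rps-11 RNAi turned from down in camera to up in fry (signed -log10 p of 0.26), its median being -0.25 and its mean 0.09. Camera compares a list with the other genes, and the median change of all genes was 0.28 in this comparison. Fry makes no such comparison, so a list can be down in camera with a mean above 0.

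Some values of the named genes turned sign under another setting. After median-of-ratios scaling the log2 change of rps-11 at 120 h of egl-45 RNAi was -0.20, that of the calcium pump gene sca-1 at 48 h of rps-11 RNAi -0.014, and that of egl-45 from 48 h to 120 h of rps-11 RNAi -0.014. After quantile normalization egl-45 was at 0.025 and 0.019 at 48 h and 120 h of rps-11 RNAi and at -0.0061 between these times, rps-11 at 0.012 between the times of egl-45 RNAi, and cyp-14A4 at -0.0896 at 120 h of rps-11 RNAi. Leaving out 1 library gave egl-45 between the times of rps-11 RNAi a range of -0.021 (without rps-11 RNAi 48 h replicate 3) to 0.077 (without rps-11 RNAi 48 h replicate 1). Of these, sca-1 (0.24) and cyp-14A4 (0.78) were called as deposited and not after the change of sign, and the cause was not tested.

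With each library left out in turn, 44 of 2745 list results and 47 of 11790 named-gene results lost their call. The counts of called genes ranged from 9976 to 10698, 11555 to 12085, 10465 to 11073 and 11747 to 12232 against the control (egl-45 at 48 h and 120 h, rps-11 at 48 h and 120 h), from 8328 to 9288 and 9060 to 9879 between the times, from 5518 to 6688 and 8131 to 9094 between the treatments, from 4455 to 5489 for the difference in change and from 6822 to 7286 for all 4 comparisons. Called lists ranged from 20 to 23, 20 to 21, 20 to 22 and 18 to 21 against the control, from 21 to 24 between the times of either treatment, from 22 to 25 and 20 to 23 between the treatments and from 11 to 14 for the difference in change.

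The replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at -0.32 to 0.22, over 0.1 in 5 of 30 pairs, and those of differently numbered ones at -0.26 to 0.41. With the number as a replicate block, 10437, 11923, 10909 and 12087 genes were called against the control, 8989 and 9745 between the times, 6379 and 8702 between the treatments, 5061 for the difference in change and 7182 in all 4 comparisons; lists called were 21, 21, 21, 18, 22, 22, 24, 20 and 12 in the same order.

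Depth limits genes with few reads: where a gene is listed at 0 in all control libraries, as 22 of the 41 tested sperm genes were, the size of its change depends on the pseudocount.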

Other observations

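The test of hsp-6 and hsp-60 beside tbb-6 was chosen after the result was seen, and the propionate shunt genes were chosen after the fall of acdh-1 was seen but before their own values were.

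Nuclear hormone receptor genes were higher as a list at 48 h of egl-45 RNAi than in the control. Across 194 nuclear hormone receptor genes, 134 rose, 17 fell and 43 were not called (median 0.58, 135 risen and 17 fallen adjusted over the list alone, camera adjusted p = 4.7e-05, adjusted p = 0.24 with an estimated correlation). The same list was higher at 48 h of rps-11 RNAi. Of 194 nuclear hormone receptor genes, 151 rose, 15 fell and 28 were not called (median 0.54, 152 risen and 15 fallen adjusted over the list alone, camera adjusted p = 8.3e-06, adjusted p = 0.34 with an estimated correlation). The receptor gene nhr-247 rose by 2.67 at 48 h of rps-11 RNAi, while nhr-68 changed by -2.72. Replication histones were lower at 48 h of egl-45 RNAi. Among the 26 replication histone genes, 15 fell, 6 rose and 5 were not called (median -0.67, camera adjusted p = 0.0084, adjusted p = 0.24 with an estimated correlation). The histone gene his-3 changed by -2.5. Glucuronosyltransferase genes, which detoxify, were higher at 48 h of egl-45 RNAi. Across 58 glucuronosyltransferase genes, 35 rose, 13 fell and 10 were not called (median 0.54, camera adjusted p = 0.028, adjusted p = 0.49 with an estimated correlation). At a mean FPKM of at least 5 these 2 calls at 48 h of egl-45 RNAi, of histones and of glucuronosyltransferases, were lost. Glucuronosyltransferase genes were higher at 120 h too. Of 58 glucuronosyltransferase genes, 42 rose, 14 fell and 2 were not called (median 0.97, 43 risen and 14 fallen adjusted over the list alone, camera adjusted p = 0.029, adjusted p = 0.46 with an estimated correlation). Here ugt-37 rose by 5.19 and ugt-63 changed by -2.59. Genes of sugar metabolism were lower at 120 h of rps-11 RNAi. Of 32 glycolysis, gluconeogenesis and trehalose genes, 20 fell, 8 rose and 4 were not called (median -0.55, camera adjusted p = 0.0013, adjusted p = 0.59 with an estimated correlation). That call was lost under quantile normalization (camera adjusted p = 0.17). The phosphoglycerate kinase gene pgk-1 changed by -1.35 and pck-3 rose by 2.67.

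The small heat shock genes hsp-12.6, sip-1 and hsp-12.3 rose by 5.57, 5.41 and 4.83 at 120 h of rps-11 RNAi, although the list of 21 cytosolic heat shock genes was not called (13 rose, 2 fell, camera adjusted p = 0.27). After quantile normalization that list passed the test as higher (camera adjusted p = 0.013). Of the stage timing genes, the period homolog lin-42 changed by -4.61 and -4.73 under egl-45 RNAi and by -2.67 and -2.45 under rps-11 RNAi, at 48 h and 120 h. The fatty acid desaturase gene fat-5 rose by 4.15, 4.85, 2.82 and 3.11 in the same order, and the glycerol-3-phosphate dehydrogenase gene gpdh-1, of the osmotic response, by 4.15 at 48 h of egl-45 RNAi.

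The fall of acdh-1 in all 4 comparisons with the control may belong to a lower propionate shunt. Of the other 4 genes of that pathway, 3 were called lower in all 4 comparisons: ech-6 (from -1.2 to -1.94 on the log2 scale), hach-1 (from -1.23 to -1.72) and hphd-1 (from -1.92 to -2.53). The last of the 4, alh-8, was higher under rps-11 RNAi, by 0.45 at 48 h and 0.64 at 120 h, and lower at 120 h of egl-45 RNAi (-0.21). The receptor gene nhr-68, an activator of the shunt, changed by -1.89, -2.79, -2.72 and -2.97, whereas its partner nhr-10 was higher in 3 comparisons and was not called at 120 h of egl-45 RNAi (-0.04). Both receptor genes were added to this comparison after their values were seen.

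The rise of tbb-6 might have come with a general mitochondrial unfolded protein response, but its chaperone genes hsp-6 and hsp-60 were lower in all 4 comparisons, the highest of their 8 log2 changes being -0.66. Relative to the 24 h control, this argues against such a response at the level of these transcripts. No control was sampled at 48 h or 120 h, so a response against animals of the same age cannot be judged.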
